A study of Saccharolobus islandicus REY15A with 6 samples.

How the data were processed

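RNA sequencing libraries were made from Saccharolobus islandicus REY15A, a thermoacidophilic archaeon that grows in acidic hot springs. Per the labels, 3 libraries came from cells in which aCcrK was overexpressed from an arabinose-induced plasmid of the pSeSD family, and 3 came from cells with the empty plasmid, 6 libraries in all. Cultures were started at an OD600 of 0.05 and collected 12 h later at an OD600 of about 0.2, per the labels' protocols. The labels' text on RNA extraction speaks of retinas, and the submitters' processing notes list the mouse build mm10 beside HISAT2 2.0.5. Neither the tissue nor that build can apply to archaeal gene identifiers, so the alignment target, the read counter and the library strandedness are taken as not given in the sources used here.

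The deposited table gives FPKM, a fragment count scaled by gene length and library size, for each library, per the file headers. FPKM times gene length gave whole multiples of a single step in every library, and 100% of values came out whole within 0.01 of a fragment. The fragments recovered in this way numbered 5550915 to 6982929 per library over the listed genes, and 1 fragment in a gene of 1 kb was worth 0.141 to 0.179 FPKM. The denominator behind the FPKM was 0.986 to 1.048 times the fragment sum, so the authors' FPKM rest on an effective library size and not on the plain sum. The authors' deposited table also holds their group means of a normalized signal, their log2 fold change, and their p-value and adjusted p-value, per the file headers. Those group means were 1.00 times the means of recovered fragments over median-of-ratios size factors. The authors' comparison was used only as a comparison with the values computed here. Recovered fragments are not molecules identified one by one, so intervals based on them cover counting error only.

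The table has 2652 genes, of which 2604 had a locus tag in the RefSeq annotation used for gene symbols and 2494 had the same start and end there. The build is not named in the sources used here, and coordinates are those of the deposited table, counted from 1 on the chromosome. Genes are named by older locus tag where the table pairs them (2515 genes) and otherwise by the newer tag. Some rows of the original table may not be analysed here.

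Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with FPKM as deposited, for the 2564 genes with a mean FPKM of at least 1 over the 6 libraries. The variance prior followed the mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are overexpression over empty plasmid on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists of 3 or more measured members out of 26 lists. An estimated correlation and the rotation test fry were alternatives. Lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. That rule took the overexpressed gene, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, every measured member of the cell division, proteasome and aCcr1 lists, and up to 4 called members of each other list with the smallest adjusted p. Lists were drawn by patterns in product descriptions. Some members were caught by letters inside another word or by a domain name. The lists were tested again without such members of the cell division, kinase and segregation lists, which left 6, 9 and 10 members. The other lists kept all their members in that test, also those described below as wrongly caught. For genes with 0 fragments in a group, the lower end of the exact 95% binomial interval of the ratio is given. For 1 to 3 fragments, the ratio is given with the whole interval.

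The alternatives were pseudocounts of 0.1 and 5, no filter and a mean FPKM of at least 10, median-of-ratios rescaling, quantile normalization, the replicate number as a block, no variance trend, a robust variance prior, each library left out in turn, and a 2-fold threshold. Added after the data were seen were voom on the recovered fragments and the gene test without genes between 775523 and 866328. A further addition was the list test without wrongly caught members of the cell division, kinase and segregation lists. Within each group, replicate pairs differed by more than sampling noise (chi-square over degrees of freedom 2.71 to 40.1), most of all control replicate 1, with 40.1 and 27.1 against the other controls, which gave 6.77 between them. So no library was treated as a copy of another. In simulated data 2361 of 2560 genes were left unchanged, and every gene had the same spread (dispersion 0.0038), a median over genes of these libraries. There limma recovered 92.5% of genes changed 1.5-fold, 87.9% of those changed 2-fold and 98.5% of those changed 4-fold. In that simulation 6.6% of calls were unchanged genes. Spread that differs between genes, a library apart like control replicate 1, and as many changed genes as called here were not simulated. These shares therefore need not hold for the real libraries. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.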

Results

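Transcript levels were measured by RNA sequencing in 6 samples of S. islandicus REY15A, 3 overexpressing the protein kinase aCcrK and 3 carrying the empty plasmid. The series asks how the archaeal proteasome and cell division are linked, and the comparison asks which transcripts differ when this kinase is overexpressed. Between 5550915 and 6982929 fragments were recovered per library, and the first principal component, with 74.7% of the variance, separated the groups. Control replicate 1 stood apart on the second component (10.5% of the variance), at 11.87 against -7.26 to 0.85 for the other libraries, and without it 1379 genes were called. Levels are FPKM as mean ± SD over 3 libraries per group, and fold changes carry their SE.

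SiRe_2030, the gene of the overexpressed kinase (1874580 to 1876589, plus strand), stood at 241.8 ± 25.8 FPKM in the empty-plasmid libraries and at 10370.3 ± 215 in the overexpression libraries, a 42.9-fold rise (log2 5.42, SE 0.08, limma with Benjamini-Hochberg adjusted p = 3.74e-09). Fragments from the plasmid and from the chromosomal copy are counted together in this value. Across the genome, 1175 of 2564 tested genes changed, of which 598 rose and 577 fell. A change of at least 2-fold was reached by 189 of them, 96 upward and 93 downward. In 57.7% of tested genes the 3 libraries of a group lay entirely beyond the 3 of the other, where chance gives 10%. The authors' deposited table called 1166 genes, and 1109 were called here in the same direction as there and 0 in the opposite direction.

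Of the 8 measured members of the cell division list 7 rose and 0 fell, and the counts adjusted over the list alone were 7 and 0. Camera called the list as higher (adjusted p = 0.00259), but with an estimated correlation the adjusted p was 0.994. The archaeal Cdv proteins, relatives of the eukaryotic ESCRT system, constrict the cell at division. The 3 neighbouring genes cdvA (SiRe_1173), cdvB (SiRe_1174) and cdvC (SiRe_1175), at 1126025 to 1128673, went from 2331 ± 219 to 3285 ± 91.4 FPKM (log2 0.50, SE 0.08), from 2647 ± 263 to 5708 ± 190 (log2 1.11, SE 0.08) and from 2557 ± 187 to 5264 ± 126 (log2 1.04, SE 0.07). The paralog SiRe_1550 had the largest rise of the list, from 9711 ± 1361 to 24125 ± 876 FPKM (log2 1.32, SE 0.11), and cdvB3 (SiRe_1388) rose from 248.4 ± 31.4 to 564.3 ± 19.0 (log2 1.19, SE 0.10). SiRe_1200, a second gene annotated cdvB1/B2, rose from 10965 ± 908 to 23577 ± 468 (log2 1.11, SE 0.09), but quantile normalization, which sets values of equal rank in each library to one value, gave -0.03. The other 2 members are CDC48-family ATPases caught by a domain name: SiRe_1832 rose by log2 0.22 (SE 0.08) and SiRe_1582 was at -0.08 (SE 0.07, adjusted p = 0.407 by limma), but was called as a fall without control replicate 1 (log2 -0.13, adjusted p = 0.0472). The call for SiRe_1832 was lost under quantile normalization (log2 0.12), with no variance trend and with the replicate block (both 0.22), without control replicate 3 (0.25) and without each overexpression replicate (0.20, 0.23 and 0.23). The gene of aCcr1 (SiRe_0197), a ribbon-helix-helix repressor of cell division genes, rose from 537.8 ± 53.7 to 861.5 ± 101 FPKM (log2 0.68, SE 0.10, adjusted p = 0.0011).

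**Figure D1:**
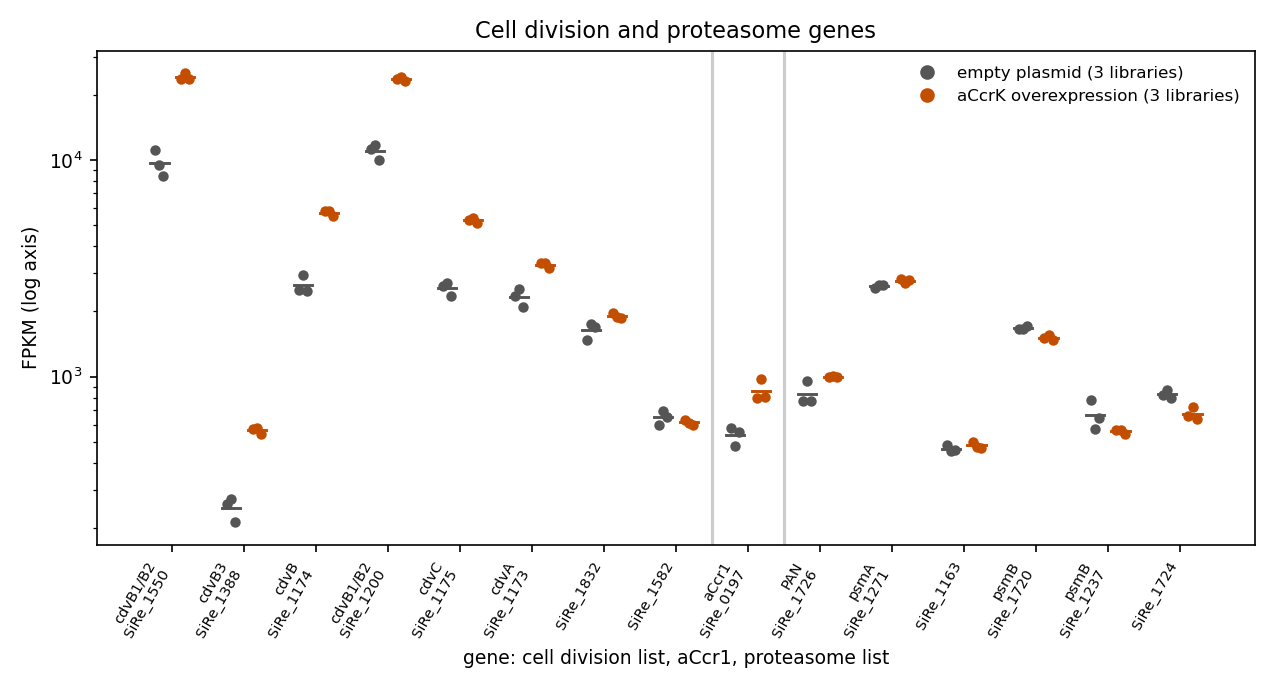
FPKM (log axis) of each cell division gene, aCcr1 and each proteasome gene in the 3 empty-plasmid and 3 overexpression libraries; points are libraries and lines are means. The 6 Cdv genes lie higher in every overexpression library than in any empty-plasmid library (for SiRe_1200 not under quantile normalization, -0.03), while 5 of the 6 proteasome genes also do not overlap between groups, with smaller differences of log2 -0.30 to 0.27.

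Proteasome genes moved little, and in both directions. Of 6 measured members 1 rose and 1 fell; adjusted over the list alone, 0 rose and 1 fell. The proteasome-activating nucleotidase SiRe_1726, the ATPase that feeds substrates to the proteasome core, went from 832.7 ± 107 to 996.7 ± 5.09 FPKM (log2 0.27, SE 0.09), a call lost, among other settings, without either control replicate 1 or 3 and without each overexpression replicate (lowest log2 0.21, without control replicate 1). The assembly chaperone SiRe_1724 fell from 827.0 ± 32.7 to 671.2 ± 44.3 (log2 -0.30, SE 0.07). The alpha subunit gene psmA (SiRe_1271) was at log2 0.08 (SE 0.06), the beta subunit genes SiRe_1720 and SiRe_1237 at -0.15 (SE 0.06) and -0.24 (SE 0.11), and the second chaperone gene SiRe_1163 at 0.05 (SE 0.06), none past the threshold. SiRe_1720 passed it as a fall without control replicate 1 (log2 -0.15), with median-of-ratios rescaling (-0.16) and with quantile normalization (-0.22), and SiRe_1237 without control replicate 2 (-0.34). The list was not called (camera adjusted p = 0.882). Among 50 measured members of the list of other proteases, 13 rose and 11 fell, including M48 metalloprotease SiRe_2008 (log2 0.86, SE 0.09) and the membrane protease gene htpX (SiRe_2013, log2 -0.53, SE 0.06). In the chaperone list 3 of 12 rose and 2 fell, and hsp20 (SiRe_0216) went from 932.8 ± 52.4 to 1375 ± 65.0 FPKM (log2 0.56, SE 0.07).

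Of 24 measured DNA replication genes 17 rose and 0 fell, and 18 and 0 when adjusted over the list alone. Camera called the list as higher (adjusted p = 1.21e-05), but with an estimated correlation the adjusted p was 0.994. Reverse gyrase SiRe_1124, which introduces positive supercoils into DNA, went from 988.3 ± 92.8 to 3156 ± 122 FPKM (log2 1.68, SE 0.08), whereas the second reverse gyrase gene SiRe_1581 was at 0.02 (SE 0.08). The DNA polymerase genes SiRe_1451 and SiRe_0615 rose by log2 1.31 (SE 0.06) and 1.16 (SE 0.08), SiRe_1740, an AAA ATPase matched by the Orc1/Cdc6 initiator pattern, by 1.10 (SE 0.07), and the replicative helicase gene mcm (SiRe_1228) by 0.89 (SE 0.07). The genes SiRe_1581 and mcm, and thyX named below, were chosen after their values were seen. Among DNA repair genes 8 of 18 rose and 3 fell, with hjc (SiRe_0930), a Holliday junction endonuclease, rising from 94.7 ± 27.0 to 470.0 ± 11.7 FPKM (log2 2.34, SE 0.17). The break repair nuclease gene SiRe_0094 fell from 274.0 ± 11.2 to 107.2 ± 4.82 (log2 -1.35, SE 0.07). SiRe_0014, which has the same annotation, rose from 172.2 ± 19.7 to 336.5 ± 13.3 (log2 0.97, SE 0.09). In the segregation and chromatin list 4 of 15 rose and 5 fell. The neighbouring ParA-family genes SiRe_0132 and SiRe_0133 rose by log2 1.75 (SE 0.09) and 0.92 (SE 0.09), and the ParA-family gene SiRe_0265 fell (log2 -0.60, SE 0.06). In nucleotide synthesis 11 of 35 rose and 7 fell. Ribonucleotide reductase SiRe_1156, which makes deoxyribonucleotides, went from 1799.6 ± 228 to 5029 ± 146 FPKM (log2 1.49, SE 0.10), and the thymidylate synthase gene thyX (SiRe_1676) rose by log2 0.99 (SE 0.13).

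Outside a stretch of the chromosome described separately, the largest fitted falls were in a peptide transporter. The substrate-binding protein gene SiRe_0418 (381638 to 384358) fell from 5035 ± 68.6 to 178.8 ± 2.55 FPKM, 28.0-fold lower (log2 -4.81, SE 0.05), and the permease genes SiRe_0417 and SiRe_0416 fell 23.1-fold and 17.8-fold. The MFS transporter SiRe_2121 fell from 620.4 ± 27.4 to 60.1 ± 2.13 FPKM (log2 -3.35, SE 0.07). Over the transporter list, 36 of 153 rose and 42 fell. In the sugar list 5 of 26 rose and 8 fell, and the glucose transporter permease genes glcT (SiRe_2179) and glcU (SiRe_2178) fell by log2 -1.11 (SE 0.09) and -1.21 (SE 0.12). Other large rises were those of the PaREP1-family gene SiRe_0911 (log2 2.53, SE 0.21), the PAPS reductase SiRe_2310 of sulfate assimilation (2.10, SE 0.15), and the hypothetical genes SiRe_0127 (2.18, SE 0.18), SiRe_0545 (2.02, SE 0.20), SiRe_0167 (1.93, SE 0.08) and SiRe_0166 (1.82, SE 0.09). The transposase gene SiRe_2612 rose from 3.44 ± 1.84 to 15.1 ± 1.97 FPKM (log2 1.96, SE 0.34).

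Of the 10 largest fitted falls, 7 were genes of a stretch of the chromosome between 775523 and 866328, the nearest ends of the genes on either side of it. That count depends on the pseudocount, being 9 with a pseudocount of 0.1, 4 with 5 and 8 with voom. SiRe_0839 (804207 to 804374) stood at 116.8 ± 14.3 FPKM in the empty-plasmid libraries and had 0 fragments in the overexpression libraries. The lower end of its 95% interval was a 91.3-fold fall. In the same way the lower end was 99.2-fold for the methyltransferase SIRE_RS13890 and 56.7-fold for the glycosyltransferase SIRE_RS13905. It was 116-fold and 27.0-fold for the transposases SIRE_RS13910 and SIRE_RS14390, and 14.0-fold for SIRE_RS14620. For the ATPase SIRE_RS13885, not among those 10 and, like SiRe_0898 below, chosen after its values were seen, it was 29.7-fold. SIRE_RS13920, an IS607 transposase, had 241 fragments against 1, a ratio of 218 (95% interval 38.8 to 8652). Fragments of transposases may be shared with other copies of the element. Over the 12 genes of this stretch analysed here, the groups had 2041 and 7 fragments, and 6 of the 7 lay in the IS630 transposase SiRe_0898, with 1 control fragment. Of 101 genes that the reference annotation places there, 93 were not analysed here. In a cluster directly to the right (866328 to 896265), chosen after its values were seen, 18 of 27 genes rose and 1 fell, with a median log2 fold change of 0.61. SiRe_0902, SiRe_0911 and hjc (SiRe_0930), named under other groups, lie in it. Each overexpression library therefore differs from the controls in this stretch as well as in its plasmid, which applies to every gene group described here.

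**Figure D2:**
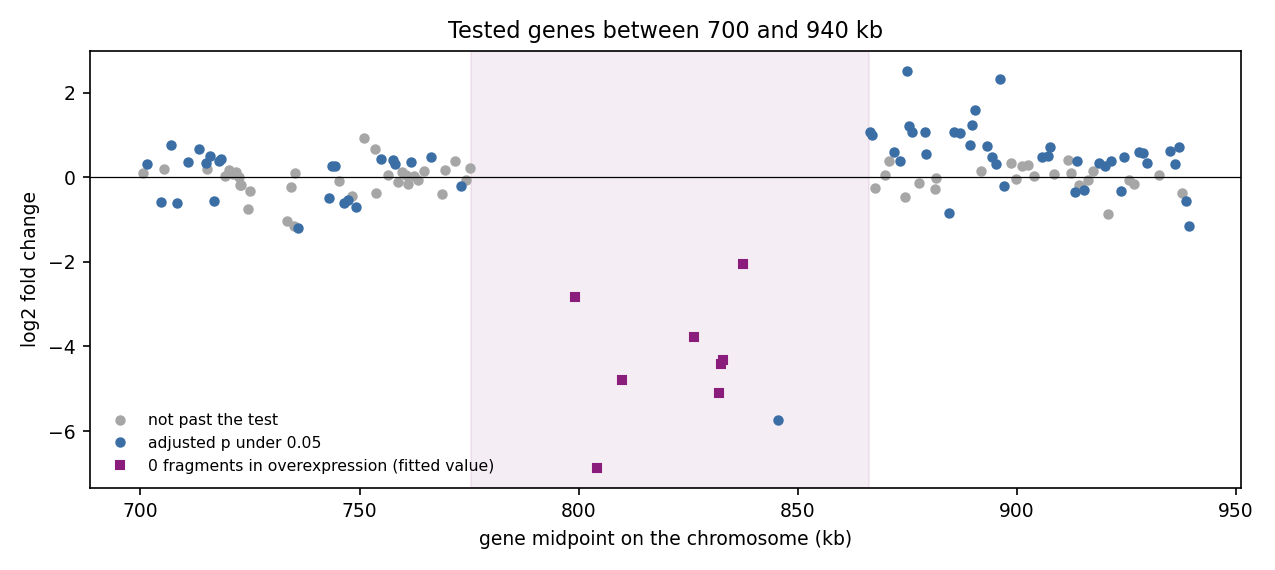
Log2 fold change (overexpression over empty plasmid) against position on the chromosome (kb) for tested genes around the stretch from 775523 to 866328 (shaded); points are genes, and squares have 0 overexpression fragments, with fitted values that are no bounds. The 9 tested genes inside the shaded stretch all lie below 0, and SiRe_0839 lies lowest at -6.87.

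**Figure D3:**
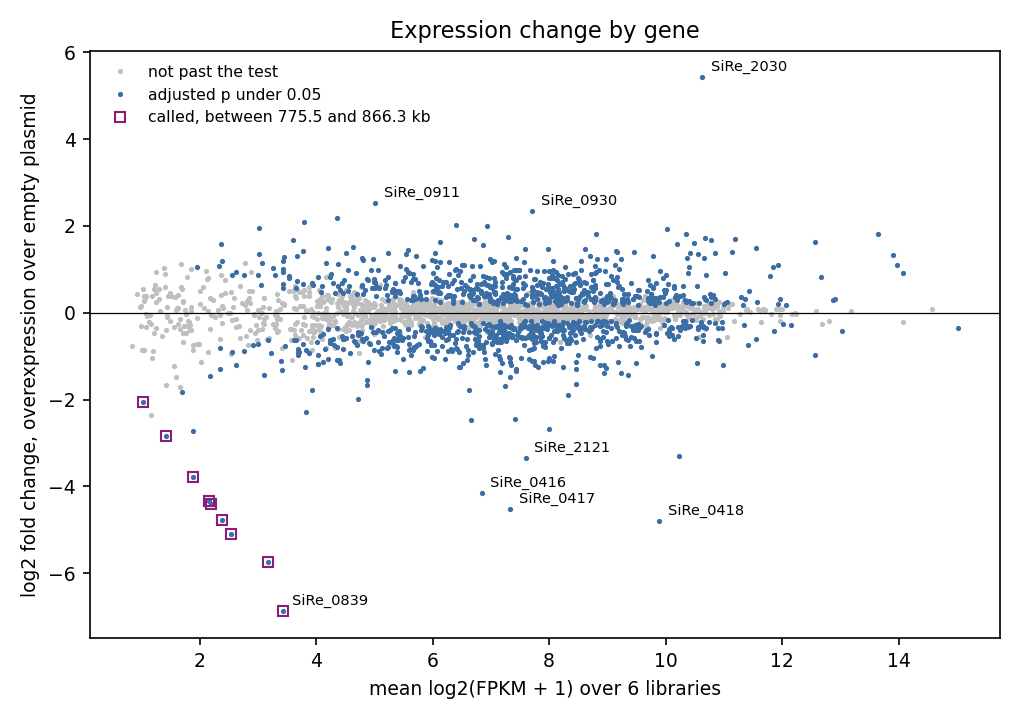
Log2 fold change (overexpression over empty plasmid) against mean log2(FPKM + 1) for the 2564 tested genes, 3 libraries per group; blue points passed the test and squares mark called genes between positions 775523 and 866328. SiRe_2030 lies highest at 5.42 and SiRe_0418 at -4.81; values of squared genes with 0 overexpression fragments depend on the pseudocount.

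In respiration 11 of 48 members rose and 11 fell. The genes soxA (SiRe_2548), soxB (SiRe_2549) and soxC (SiRe_2550) of a terminal oxidase fell by log2 -1.16 (SE 0.07), -1.16 (SE 0.08) and -1.13 (SE 0.06), and soxA went from 2222 ± 92.3 to 998.4 ± 80.6 FPKM. In central carbon metabolism 17 of 53 rose and 12 fell. There, lysS (SiRe_1108), annotated as homocitrate synthase and caught by the words citrate synthase inside that name, rose by log2 1.23 (SE 0.08). The 3-isopropylmalate dehydratase genes SiRe_0260 and SiRe_0259, caught by the word malate inside that name, rose by 0.71 (SE 0.07) and 0.64 (SE 0.06). SiRe_0260 is counted in the amino acid list as well. The isocitrate lyase gene aceA (SiRe_0742), of the glyoxylate shunt, rose by 0.68 (SE 0.06). In amino acid synthesis 8 of 38 rose and 9 fell, with the glutamate synthase genes SiRe_1331 and SiRe_1332 rising by log2 1.38 (SE 0.10) and 0.96 (SE 0.10). SiRe_0574, annotated as a lactonase and caught by the word homoserine, fell (-1.27, SE 0.11). In the lipid list 9 of 34 rose and 9 fell, and the 3-hydroxyacyl-CoA dehydrogenase SiRe_2247 fell from 236.8 ± 4.10 to 107.6 ± 8.07 FPKM (log2 -1.13, SE 0.07).

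Among transcription machinery genes 5 of 21 rose and 3 fell, and the IIB-type initiation factor SiRe_1144 went from 1046 ± 106 to 2520.1 ± 114 FPKM (log2 1.27, SE 0.08), while another, SiRe_1717, fell (-0.62, SE 0.12). Of 103 transcription regulators 18 rose and 30 fell. The archaellum regulator gene arnR (SiRe_0128) rose from 60.4 ± 8.55 to 243.4 ± 28.8 FPKM (log2 2.00, SE 0.13), and lrs14 (SiRe_1948) fell from 8506 ± 506 to 4364 ± 167 (log2 -0.96, SE 0.07). The ribosomal protein list had 7 rises and 5 falls among 67 members and, adjusted over the list alone, 0 and 2. The 5 falls include rimI (SiRe_1785, log2 -0.61, SE 0.06), annotated as an N-acetyltransferase of a ribosomal protein and caught by that name. The list of translation factors and aminoacyl-tRNA synthetases had 9 rises and 4 falls among 40, the largest of the named rises in the tryptophan tRNA ligase SiRe_1548 (log2 0.87, SE 0.08). Its falls include SiRe_1735 (log2 -0.65, SE 0.08), annotated as a transcriptional regulator and counted in the transcription machinery list as well. In the kinase and phosphatase list 8 of 18 rose and 4 fell, but the rises include the overexpressed SiRe_2030 itself, and several members were ATPases caught by letters inside another word. Of its kinases, chosen after their values were seen, SiRe_1639 and SiRe_0101 rose by log2 0.50 (SE 0.08) and 0.41 (SE 0.08), and SiRe_2056 fell (-0.42, SE 0.07).

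In the motility and pili list 5 of 11 rose and 2 fell. Flagellin SiRe_0124, the archaellum filament protein, rose from 32.3 ± 4.07 to 81.4 ± 2.26 FPKM (log2 1.31, SE 0.11), and SiRe_0180, a type II secretion F-family gene, fell (-1.05, SE 0.06). CRISPR-Cas genes split, with 9 of 24 rising and 7 falling. The type III-B genes cmr4 (SiRe_0602) and cmr5 (SiRe_0601) rose by log2 0.71 (SE 0.08) and 0.70 (SE 0.13), and the CRISPR repeat-binding gene cbp1 (SiRe_1547) fell (-1.24, SE 0.13). In the S-layer and glycosylation list 6 of 27 rose, among them the glycosyltransferase SiRe_0399 (log2 0.94, SE 0.05). In the same list 5 fell, among them SIRE_RS13905 of the stretch between 775523 and 866328. The toxin and antitoxin list had 18 rises and 9 falls among 65, and the HEPN-domain gene SiRe_0902 rose by log2 1.08 (SE 0.09). Its rises include genes with other annotations. SiRe_0062, an SMC-family ATPase counted in the segregation list as well, rose by 0.95 (SE 0.10), and SiRe_0086, an ATP/GTP-binding protein, by 0.80 (SE 0.08). Transposases had 7 rises and 11 falls among 66, and reads of their copies cannot be assigned with certainty. The falls include SIRE_RS13910, SIRE_RS14390 and SIRE_RS13920, which lie in that stretch. Stable RNA, a sign of RNA quality and rRNA removal, took 1.87% of fragments in control replicate 1, 0.827% and 1.08% in the other controls and 1.02% to 1.205% with overexpression. Of its 30 genes 0 rose and 1 fell, the alanine tRNA SiRe_t0002 (log2 -0.70, SE 0.20), with 5 to 12 fragments per library, whose call was lost with voom (log2 -0.67, adjusted p = 0.189), and without control replicate 1 or 3 or overexpression replicate 2 or 3 (smallest fall log2 -0.58, without control replicate 1).

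Of 25 lists tested with camera, only cell division and DNA replication passed an adjusted p of 0.05, and with an estimated correlation 0 lists did (adjusted p = 0.994 for every list, and 0 lists with an unadjusted p under 0.05), while fry called 11. Adjusted over the list alone, rises and falls numbered 5 and 6 in segregation and chromatin, 9 and 3 in translation factors, 12 and 7 in nucleotide synthesis, 6 and 9 in the sugar list, 37 and 42 in transporters, 9 and 10 in CRISPR-Cas, 5 and 11 in transposases, 10 and 10 in the lipid list and 0 and 0 in stable RNA. In the other lists whose count adjusted over the list alone is not given here, it equalled the count over all genes. The mean and the median log2 fold change had opposite signs in the lists of segregation, transcription machinery, transcription regulators and other proteases. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples.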

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

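The tests with voom, without genes between 775523 and 866328, and without some of the wrongly caught list members were chosen after the data were seen. The count of 1175 changed genes was 936 to 1379 when 1 library was left out (lowest without overexpression replicate 2, highest without control replicate 1) and 1074 to 1218 under the other settings run, except the 2-fold threshold, which by construction left 189. Replicate numbers did not pair the samples: deviations of libraries with the same number correlated at -0.06, 0.05 and 0.08. With the replicate block 1074 genes were called. The count of 2 called lists stayed at 2 under each setting run except an estimated correlation, which gave 0, and fry, which gave 11 because it asks whether a list's genes move one way and not whether they differ from other genes. The adjusted p of the cell division list was 0.00118 to 0.00739 with 1 library left out and 0.994 with an estimated correlation of 0.469. That of the replication list was 2.03e-06 to 0.000301, and 0.994 with an estimated correlation of 0.326. Of 1826 values of named genes, 1800 kept their direction and side of the threshold, 20 lost the call, 5 gained it and 1 reversed: SiRe_1200, at -0.028 (log2) under quantile normalization. Of 286 values of the other lists 277 kept theirs and 9 gained a call, all with fry. At this depth no fold is given where both groups have 3 fragments or fewer.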

Other observations

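Some gene groups stood out only after their values were seen, and the tests added in this part were chosen after the result was seen. The calls of single genes, and the adjusted p of the cell division and replication lists, come from tests fixed beforehand. All 8 measured genes of the archaellum cluster (SiRe_0118 to SiRe_0124 with arnR, SiRe_0128) rose, with a median log2 fold change of 1.12. All 7 genes of a sulfate assimilation cluster (SiRe_2307 to SiRe_2313) rose, with a median of 1.19, among them nitrite/sulfite reductase SiRe_2311 from 7.36 ± 0.174 to 21.4 ± 3.11 FPKM. In contrast, 11 of 12 genes of a heterodisulfide reductase-like cluster (SiRe_0970 to SiRe_0981), of a kind linked to sulfur oxidation, fell, with a median of -1.15, and SiRe_0974 went from 550.4 ± 66.7 to 224.2 ± 23.6 FPKM. All 4 genes of the SoxABC oxidase cluster fell (median -1.14), and all 6 genes of the peptide transporter cluster SiRe_0413 to SiRe_0418 fell (median -3.42). None of these 5 clusters was a list fixed beforehand, so their direction is a description.

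A set of 10 genes, made of UV-induced pili and DNA import genes and the initiation factor SiRe_1717, had 7 falls and 0 rises (median log2 -0.86). The ups pili and Ced system exchange DNA between cells after damage. The pilin gene upsA (SiRe_1881) went from 1091 ± 278 to 398.9 ± 31.6 FPKM (log2 -1.42, SE 0.16), and SiRe_2100, annotated cedA, from 52.0 ± 8.26 to 12.2 ± 1.17 (log2 -1.99, SE 0.15). Camera gave an unadjusted p of 7.24e-05 for the set, and of 0.0353 with an estimated correlation, but its genes were chosen after some of the values were seen.

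Between 775523 and 866328, bounds chosen after the values were seen, the overexpression libraries had 7 fragments, where 1848 would be expected at the control level, which argues against sampling. Outside that stretch 0 genes with 30 or more control fragments were at 0 in the overexpression libraries, which argues against a loss of reads across the genome. All 7 genes of the table with 30 or more control fragments and 0 with overexpression, found without regard to position, lay between 798733 and 832908. They were neighbours among the genes analysed here at that depth, with 0 genes between them that kept overexpression fragments. That test does not cover the rest of the stretch. To the right, SIRE_RS13920 at 845308 kept 1 fragment against 241, and the transposase SiRe_0898 at 862407 had 6 against 1 in the controls. Of the 101 reference genes of the stretch, 93 were not analysed here. A chromosomal segment absent from the overexpression cells, holding at least these 7 genes, is a candidate explanation, and its ends are not known. Silencing of the whole stretch was not tested and stays open, since no DNA was measured.

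The 32 cell division and DNA replication genes, pooled because camera had called these lists, had a median log2 fold change of 0.51, and 24 rose. Scaling between libraries is argued against by the lowest median over 5 scalings and pseudocounts, 0.45, and expression level or gene length as the whole cause by other genes of like level and length: 0 of 10000 lists drawn from these had a median as high, and theirs lay around 0.04. The draws ignore correlation between genes and the choice of the lists, so they give no p-value for the rise, and each list had an adjusted p of 0.994 with an estimated correlation. The difference in the region between 775523 and 866328 stays open: 0 overexpression libraries kept it at 0.5 of the control level or more, so the plasmid and the region cannot be told apart as the source of these rises. The kinase itself, and a shift in the share of cells in each cell cycle stage, were not tested apart from it.

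The orotate phosphoribosyltransferase gene pyrE (SiRe_1392) fell from 271.1 ± 62.9 to 94.7 ± 1.04 FPKM and the orotidine decarboxylase gene SiRe_1391 beside it from 8.19 ± 0.667 to 4.03 ± 0.885; both serve as plasmid markers in this genus. A pathway-wide fall of pyrimidine synthesis is argued against by the lowest log2 fold change among 4 neighbouring pyrimidine genes, 0.34. An equal loss of both marker transcripts stays open: the log2 fold changes differed by -0.60 (SE 0.26), or 2.29 standard errors, which alone would argue against it. The comparison was extended to 4 settings only after that value was seen, because the low level of SiRe_1391 makes its fold depend on the pseudocount, and the difference was -0.90 (SE 0.19), or 4.61 standard errors, with a pseudocount of 5, 1.58 standard errors with 0.1, and -0.48 (SE 0.31), or 1.54 standard errors, with voom. These standard errors treat the 2 genes as independent, although both were measured in the same 6 libraries, so the sizes in standard errors are approximate. Which marker these plasmids carry is not given in the sources used here.

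Among the 10 splits of the 6 libraries into 3 and 3, 1 called 1175 or more genes, the real one, and the highest of the others called 0. For gene lists, 7 of the 10 splits, the real one with its 2 lists among them, called 2 or more, and the highest of the others called 7. For genes, the share cannot go below 0.1 with 10 splits, so this test cannot decide on chance. For lists, other splits called as many or more, so the count of 2 called lists does not set the real split apart from them.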
